A study of Arabidopsis thaliana with 12 samples.

How the data were processed

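RNA levels were measured on 12 Affymetrix Arabidopsis arrays, each hybridised with biotin-labelled cRNA made from total RNA of the aerial part of 10-day-old seedlings that overexpressed CCA1. Seedlings had been grown on agar with 1% sucrose under 16 h of light and 8 h of dark, per the labels' protocols, and were harvested at 4 times of day with 3 arrays each. Zeitgeber time (ZT) counts hours from lights on, so ZT6 and ZT12 lay in the light, ZT18 lay in the dark and ZT0 was the moment of lights on. Wild-type seedlings, which the design text also names, were not analysed here.

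The deposited values were log2 expression values per probe set, with 1 value per array and no pooling of replicates. R 3.1, GCRMA and affy 1.42.3 are named in the submitters' processing notes, per the labels, with no role or order. Settings of the background correction and summary were not given in the sources used here. All arrays shared a floor of 2.06, at which 24.4% to 26.5% of values lay, and array medians ran from 6.27 to 6.43. No detection calls were used here, so a value of 4 served as the detection limit. The number of arrays limits the precision of every value.

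Groups were taken from the title of each sample. Of 4 labels that carry a time, 3 gave the same time on every array (title, source name and description). The 1 other label, a characteristic for the time of harvest, differed from them on 9 of 12 arrays and was used only as an alternative. Nothing in the labels says whether replicate arrays came from separately grown plants, so p-values measure the spread between these arrays, which may be technical in part. No array was a copy of another: within a pair of arrays, 73 to 190 of 14016 probe sets had exactly equal values, with no tolerance.

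Of 22810 probe sets, 64 chip controls were left out, and 14016 of the remaining 22746 reached 4 on at least 3 arrays and were tested. The platform annotation table paired 13513 probe sets with 1 gene and 503 with several, and did not list 8730, which are unnamed here. Among the tested probe sets these numbers were 7610, 299 and 6107. Names were updated through Entrez identifiers to the RefSeq table of assembly TAIR10.1, where 13285 of 13355 genes matched; the other 70 kept the symbol of the platform table. That table does not name a probe set for CCA1 itself, so its level is not analysed here. Because the files name no genome build, no coordinates are given. Each gene was represented by the probe set with the highest mean over the 12 arrays, which left 7571 genes.

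Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit with a mean per time, followed by eBayes with a mean-variance trend. All 12 arrays entered the fit so that the 4 times shared 1 estimate of the spread. A moderated F-test compared the 4 times, and moderated tests (two-sided) made 6 comparisons: 4 between times 6 h apart and 2 between times 12 h apart. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05, and every adjusted p given for a gene comes from this limma fit. Changes are log2 differences with the standard error (SE) of the fit. Where all 3 arrays of the dimmer time lay under 4, the fold is given as "at least", from the mean of the bright time against the mean of the higher of 4 and the measured value on each dim array.

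Gene lists were tested with limma camera at its preset correlation of 0.01 on lists with at least 5 measured members, adjusted over all lists and the 6 comparisons. The 24 lists fixed first named 395 genes, of which 57 had a named probe set and 50 were tested, so only 2 lists reached 5 members. For that reason 32 gene families were added by symbol, from the annotation table and before expression values of their members were examined. Of these, 27 could be tested. Only 1535 genes had a symbol, so a family here holds only members with one, and its counts do not cover the whole family. Camera was repeated with a correlation estimated from the arrays, and fry was run as well, which asks whether the genes of a list move 1 way on balance and does not compare them with other genes.

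Named genes followed a fixed rule. It asked for CCA1, for all core clock genes with a probe set, and for the 8 largest rises and 8 largest falls in each comparison of times 6 h apart. It also took the 5 and 5 largest for times 12 h apart, the 10 largest ranges for the F-test, and up to 4 members of each list past the threshold. A gene taken for its size needed every array of the higher time above every array of the lower. No fixed list passed by camera (0 calls, with 4 at an unadjusted p under 0.05 and 7 by fry), so the rule took none of their members. The members of fixed lists named in the text, other than the core clock genes, and all other genes outside the rule were chosen after their values were seen.

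The code was tested on simulated data with the real means and spread. Over 14016 simulated probe sets, the comparison of ZT18 with ZT12 recovered 75% of 100 probe sets changed 2-fold and 99% of 100 changed 4-fold, with 9 false calls. The simulated F-test recovered 75% and 99%, with 10 false calls. Camera at the preset correlation, on 7571 genes, found all 3 list comparisons shifted by 0.5 and none of the 159 others. It was not tried there with an estimated correlation. These simulations drew probe sets independently of each other, with normal noise and no floor. For limma, only 100 probe sets were changed at each size, all at ZT18. Far more probe sets passed in 5 of the 6 comparisons of the real data, so the shares recovered and the false calls need not hold there.

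Other settings listed before the data were examined were no filter and a filter at 6, a further quantile normalization, centring on array medians, no trend, a robust trend, the replicate number as a block, leaving out each array, the contradicting time label, a fit to the 6 arrays compared, and stricter thresholds. For the 24 fixed lists they were an estimated correlation, fry and the mean of all probe sets of a gene. The settings repeated for the added families, the estimated correlation included, were chosen after camera had been run on them, although the families themselves were not. A covariate for the 3' to 5' difference of control probe sets, and F-tests without the ZT18 or the ZT0 arrays, were also added after seeing the data. Figures were drawn with matplotlib 3.10.9.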

Results

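The series profiled transcripts through a day in Arabidopsis thaliana seedlings that overexpress CIRCADIAN CLOCK ASSOCIATED 1 (CCA1), a MYB transcription factor of the circadian clock. It asked how transcript levels in this line vary over a 24 h light/dark cycle. The 12 arrays comprised 3 from each of ZT0, ZT6, ZT12 and ZT18. Between arrays of the same time, the SD of the difference over 14016 probe sets was 0.222 to 0.499 on the log2 scale. Between arrays of different times it was 0.325 to 0.482 for ZT6 against ZT12 and at least 0.581 for all other pairs. The first principal component held 62.3% of the variance and placed all 6 ZT6 and ZT12 arrays on the opposite side from all 6 ZT18 and ZT0 arrays. Values below are means ± SD of log2 expression (n = 3 arrays per time).

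Transcript levels differed widely among the 4 times. Transcripts with the largest ranges included COR27, a cold-regulated gene also controlled by the clock, which was highest at ZT0 (12.53 ± 0.22) and lowest at ZT6 (6.32 ± 0.76), a 74.2-fold range. AT1G13650 was highest at ZT6 (8.92 ± 0.16) and lowest at ZT0 (2.17 ± 0.15), a range of at least 30.3-fold. AT1G47400, which encodes a small peptide of the iron-deficiency response, fell from 11.29 ± 0.40 at ZT12 to 4.87 ± 0.63 at ZT18, an 85.5-fold range. The cell-wall genes XTH33 and EXPA16 were highest at ZT0, at least 29.8-fold above ZT6 and at least 49.9-fold above ZT12 respectively. In the limma F-test, 9827 of 14016 probe sets (70.1%) passed, and 4524 of these spanned at least 2-fold between their highest and lowest time. Of the 4524, 1364 peaked at ZT0 (30.2%), 1119 at ZT6 (24.7%), 1078 at ZT12 (23.8%) and 963 at ZT18 (21.3%). ZT0 was also the most common time of the lowest mean, for 1598 (35.3%). A peak is the time with the highest mean and was not tested against the next highest. Only 297 of 14016 probe sets passed between ZT6 and ZT12, so peaks at ZT6 and at ZT12 were mostly not told apart.

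Of the core clock list, 2 of 26 genes had a named probe set. GIGANTEA (GI), which acts in the clock and in photoperiodic flowering, rose from 6.37 ± 0.25 at ZT0 to 8.62 ± 0.06 at ZT6, a log2 change of 2.25 (SE 0.18, adjusted p = 5.09e-07). It was 8.31 ± 0.10 at ZT12 and fell to 7.82 ± 0.36 at ZT18 (adjusted p = 0.0340), a call that was lost with the 3' minus 5' covariate described below (adjusted p = 0.375) and without ZT18 replicate 2 (adjusted p = 0.141). AT5G52660, a MYB-like gene related to CCA1, rose from 7.57 ± 0.16 at ZT0 to 8.09 ± 0.05 at ZT6 (adjusted p = 0.00658) and fell from 8.00 ± 0.22 at ZT12 to 7.36 ± 0.12 at ZT18 (adjusted p = 0.00224). AT1G69570, a CYCLING DOF FACTOR gene and the only measured member of the list of photoperiod and clock output genes, ran the other way, with 9.43 ± 0.17 at ZT0 and 6.21 ± 0.19 at ZT6.

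**Figure D1:**
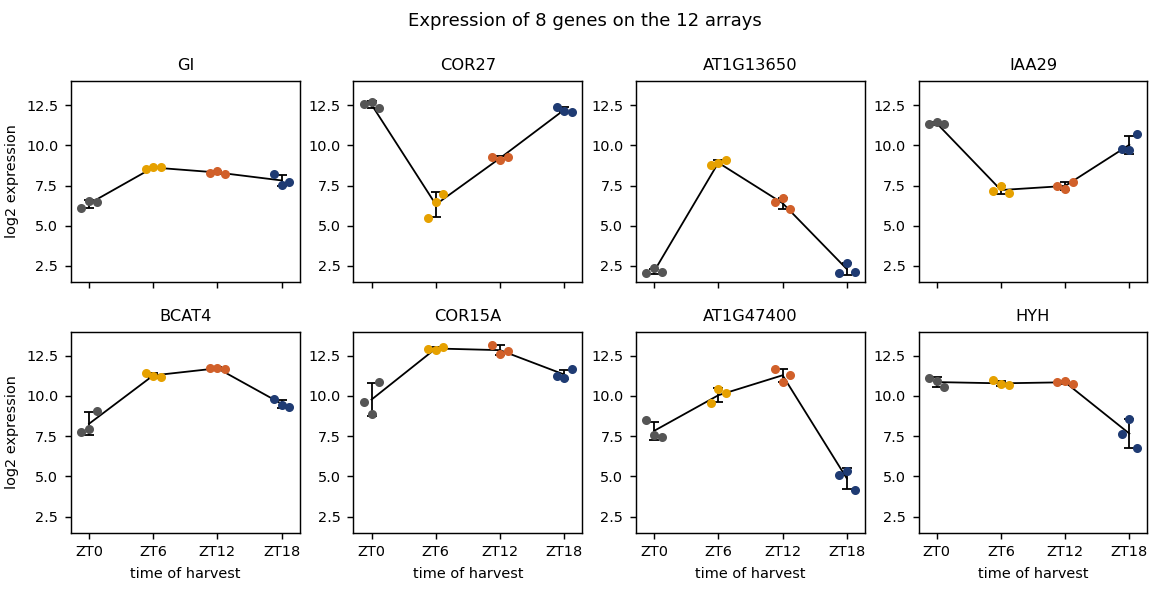
Log2 expression (vertical axis) of 8 genes at the 4 times of harvest (horizontal axis), with a point per array and a line through the means with SD bars. COR27 and IAA29 were lowest at ZT6, AT1G13650 was highest at ZT6, and HYH was lower at ZT18 (7.66 ± 0.88) than at the other times.

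The first 6 h of light, ZT6 against ZT0, gave the most calls of the 6 comparisons. Genes that rose included AT3G44450, a gene for an inhibitor of cryptochrome photoreceptors (from 3.28 ± 0.34 to 9.08 ± 0.19, at least 33.8-fold), and AT3G44970, a cytochrome P450 gene (at least 21.7-fold). AT1G60590 and AT1G10640, which encode pectin lyase-like proteins, rose 45.6-fold and 45.1-fold, and AT2G27420, a cysteine proteinase gene, rose 42.0-fold. Genes that fell included COR27 (74.2-fold), XTH33 (at least 29.8-fold), EXPA16 (at least 49.9-fold), AT1G19530 (24.9-fold) and AT3G15440 (at least 19.6-fold). All of these had adjusted p-values of at most 7.56e-07. Altogether 3871 probe sets were higher at ZT6 and 3980 were lower, and 3009 of them changed at least 2-fold.

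Between ZT0 and ZT6 the 3 measured light-harvesting genes, the 4 nuclear photosystem genes, the 3 Calvin cycle genes and the 2 starch synthesis genes all rose, also when adjusted over the list alone. The examples from these and the other fixed lists were chosen after their values were seen. LHCB4.3 rose from 5.64 ± 0.16 to 7.41 ± 0.14, SBPASE, the gene for sedoheptulose bisphosphatase, from 12.98 ± 0.20 to 13.80 ± 0.06, and APL3, a subunit of ADP-glucose pyrophosphorylase, from 3.63 ± 0.77 to 6.93 ± 0.17. Of 6 chlorophyll synthesis genes 4 rose, over all genes as well as adjusted over the list alone, led by CHLI2, a magnesium chelatase subunit (11.32 ± 0.04 to 12.46 ± 0.09). Camera did not call that list (adjusted p = 0.0722, and adjusted p = 0.578 with an estimated correlation). Of 2 starch degradation genes PWD rose (adjusted p = 0.0492), and both did when adjusted over the list alone. The call of PWD was lost with no filter, median centring, no variance trend or a robust trend, and without any single array except ZT18 replicate 1 and ZT0 replicate 3. None of the 3 plastid ribosomal protein genes passed by limma, also adjusted over the list alone. Of 40 plastid-encoded photosynthesis genes, an added family, psbD and psbI were also chosen in this way: psbD rose (8.85 ± 0.40 to 9.85 ± 0.64), psbI fell (11.21 ± 0.22 to 10.52 ± 0.37) and 38 did not pass, with a list mean of -0.18 (camera adjusted p = 0.538, and adjusted p = 0.890 with an estimated correlation). Both calls were lost with no filter and without ZT0 replicate 1, ZT6 replicate 2 or ZT6 replicate 3. All 3 measured glucosinolate genes rose, also adjusted over the list alone. BCAT4, an aminotransferase of methionine chain elongation, went from 8.27 ± 0.72 to 11.28 ± 0.13.

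Other fixed lists were mixed between ZT0 and ZT6. Of 4 cold and dehydration genes, COR15A (9.78 ± 1.01 to 12.95 ± 0.10) and COR15B (9.39 ± 0.66 to 12.39 ± 0.13) rose, COR47 fell (13.88 ± 0.13 to 13.16 ± 0.15) and LTI30 did not pass; the counts adjusted over the list alone were the same. Of 4 cell division genes, AUR1, AUR2 and PRL rose and AUR3 fell, also adjusted over the list alone. IAA29, an auxin-responsive gene and the only measured member of the shade and elongation list, fell from 11.37 ± 0.08 to 7.22 ± 0.23. AT3G15450, from the list of dark- and sugar-starvation-induced genes, fell from 12.13 ± 0.20 to 10.70 ± 0.08. Of 7 cytosolic ribosomal protein genes 2 fell and 5 did not pass, with equal counts when adjusted over the list alone. PYK10, the only measured gene of the root marker list, was 12.74 ± 0.24 at ZT0 and 13.14 ± 0.02 at ZT6, and rose by this test. That list had been drawn up to stand for tissue other than the aerial part. PYK10 lay far above the array medians of 6.27 to 6.43, and whether the samples held root tissue was not tested. STZ, a zinc-finger gene and the only measured member of the touch and rapid stress list, was 3.94 ± 2.27 at ZT0 and 3.14 ± 0.50 at ZT6 and did not pass. No gene of the lists for flavonoids, photoreceptors, heat shock, jasmonate and wounding, nitrogen assimilation or seed storage could be tested.

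Among the added families, 21 of 25 genes for chloroplast complex assembly and organelle RNA editing rose between ZT0 and ZT6 and none fell. CRR42 rose from 8.05 ± 0.13 to 10.68 ± 0.13, CRR21 from 7.85 ± 0.36 to 9.43 ± 0.19, PIFI from 12.24 ± 0.13 to 13.22 ± 0.09 and HCF101 from 11.96 ± 0.15 to 12.79 ± 0.12. Camera gave this family adjusted p = 7.68e-06, but adjusted p = 0.648 with an estimated correlation. Of 25 UGT glycosyltransferase genes 17 rose and 5 fell (adjusted p = 0.0292, and adjusted p = 0.651 with an estimated correlation), with UGT76E11 going from 7.07 ± 0.40 to 10.08 ± 0.13. Of 7 glutathione S-transferase genes 5 rose (adjusted p = 0.0492, and adjusted p = 0.648 with an estimated correlation), among them GSTU20 (9.86 ± 0.35 to 12.44 ± 0.14). Over the 6 comparisons camera called 19 of 162 tests of added families, and 0 with an estimated correlation. These calls therefore do not show that a family differed from other genes. Of 100 splits of the arrays, the real one included, 21 gave at least as many. The other splits mix arrays of differing times, so this share is not a rate for chance alone.

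**Figure D2:**
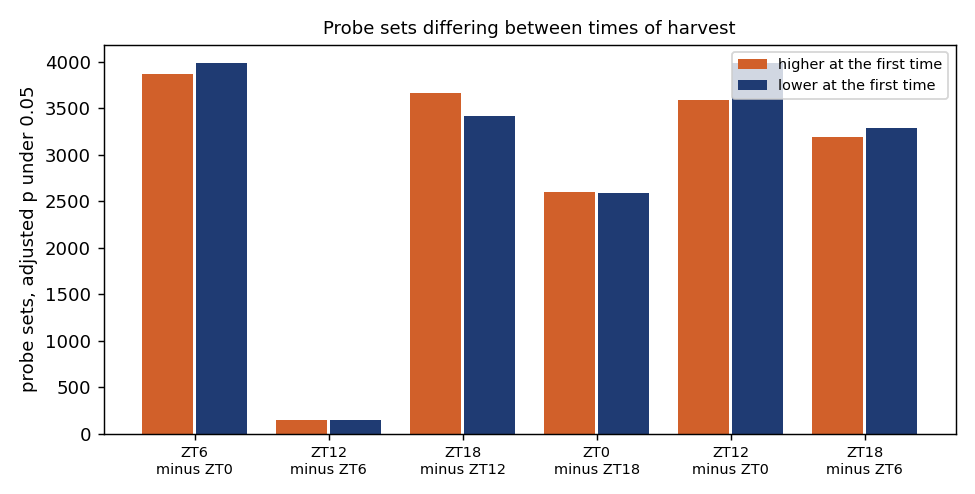
Number of probe sets (vertical axis) higher and lower at the first-named time in each of the 6 comparisons (horizontal axis), at an adjusted p under 0.05 in limma. ZT12 against ZT6 had 297 in all, and each of the other comparisons had at least 5187.

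Between ZT6 and ZT12, both in the light, fewer probe sets passed than in any of the other comparisons. COR27 rose from 6.32 ± 0.76 to 9.20 ± 0.12 (7.37-fold, adjusted p = 0.000335), AT1G07050 rose at least 3.83-fold, and AT3G25600 rose 2.89-fold (8.75 ± 0.33 to 10.28 ± 0.19). AT1G13650 fell 5.72-fold to 6.40 ± 0.35 (adjusted p = 0.000272), and AT3G46370 fell 4.43-fold. The test called 151 probe sets as higher at ZT12 and 146 as lower, with 92 changed at least 2-fold. Of the measured members of the fixed lists 1 passed over all genes, the starch degradation gene PWD (11.14 ± 0.02 to 11.63 ± 0.03), a call lost with the 3' minus 5' covariate described below, with no filter, with no variance trend, without ZT18 replicate 2 and without any 1 of the 6 ZT6 and ZT12 arrays. Adjusted over the list alone, PWD passed as higher and LHCB4.2 and both starch synthesis genes as lower. AT1G69570 and STZ, each the only measured member of its list, passed only where no adjustment applied (adjusted p = 0.171 and adjusted p = 0.0997 over all genes). Camera called the 40 plastid-encoded photosynthesis genes and the 15 plastid-encoded ribosomal protein and RNA polymerase genes as higher (adjusted p = 0.0415 for each), with no single member passing, and gave adjusted p = 0.662 and adjusted p = 0.766 with an estimated correlation. It also called 8 bZIP genes as higher (adjusted p = 0.0457, and adjusted p = 0.648 with an estimated correlation), again with no single member passing. The count of 297 moved both ways with the settings, to 752 in a fit to its own 6 arrays and to 145 with no filter. It was higher still with the replicate number as a block, as given below. With single arrays left out, the count was 165, 27 and 41 without ZT6 replicates 1, 2 and 3, and 102, 107 and 125 without ZT12 replicates 1, 2 and 3. It was 466 without ZT18 replicate 1 and 451 without ZT0 replicate 3.

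From ZT12 to ZT18, across lights off, AT1G47400 fell 85.5-fold, BHLH101, a transcription factor gene of the iron-deficiency response, fell from 9.06 ± 0.19 to 3.57 ± 0.46 (at least 33.3-fold), and AT1G60590 fell 55.9-fold. AT3G21670, a nitrate transporter gene, fell 23.8-fold from 10.52 ± 0.26 to 5.95 ± 0.46, and AT5G19730, a pectin lyase-like gene, fell at least 9.28-fold. Genes that rose included AT4G33980, a cold-regulated gene related to COR27 (5.31 ± 0.70 to 9.88 ± 0.08, 23.8-fold), and XTH33 (19.9-fold, from a dim 3.93 ± 0.47). AT1G50040 (at least 11.2-fold), AT2G31010 (21.1-fold) and the small heat-shock gene AT1G53540 (at least 10.7-fold, with 7.42 ± 1.60 at ZT18) also rose. Adjusted p-values of these genes were at most 5.45e-05. The test called 3659 probe sets as higher at ZT18 and 3419 as lower, 2225 of them at least 2-fold.

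In the fixed lists, all 3 Calvin cycle genes and all 3 glucosinolate genes fell between ZT12 and ZT18, and so did both clock genes, in each case also adjusted over the list alone. BCAT4 reached 9.51 ± 0.27 and SBPASE 13.62 ± 0.18. With the 3' minus 5' covariate, all 3 glucosinolate genes, 1 of the 2 clock genes and 0 of the 3 Calvin cycle genes still passed by limma, and the change of SBPASE was 0.017. Of 4 nuclear photosystem genes 1 fell, which was lost with the covariate, and none of the 3 light-harvesting genes passed. Of 7 cytosolic ribosomal protein genes 4 fell, by a list median of -0.29 (camera adjusted p = 0.135, and adjusted p = 0.578 with an estimated correlation), and 1 of these 4 still passed with the covariate. IAA29 rose to 10.03 ± 0.56 and AT1G69570 to 8.57 ± 0.41. In the added families, 6 of 7 glutathione S-transferase genes and 5 of 9 CYP71B cytochrome P450 genes fell and none rose. Camera gave adjusted p = 0.0155 and adjusted p = 0.0242, and adjusted p = 0.648 for each with an estimated correlation. CYP71B26 fell from 11.62 ± 0.22 to 9.16 ± 0.24. With the covariate 4 of the 6 glutathione S-transferase genes and 3 of the 5 CYP71B genes still passed. Of 25 genes for chloroplast complex assembly and organelle RNA editing 16 fell and 2 rose, and 7 of these 18 still passed with the covariate. Of 25 UGT genes 13 fell and 4 rose, and 15 of these 17 still passed. Camera called both families as lower (adjusted p = 0.0154 and adjusted p = 0.0365, and adjusted p = 0.651 for each with an estimated correlation).

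A sign of RNA quality differed at ZT18. The 3' minus 5' signal of the actin, GAPDH and ubiquitin control probe sets, which grows as RNA or its copy is shortened, averaged 3.88 ± 0.27 on the ZT18 arrays and 3.25 on the other 9 arrays. The difference was 0.63, and no other choice of 3 arrays out of 12 gave as large a difference (exact permutation test over 220 splits, two-sided, p = 0.00455). This p does not allow for the choice of ZT18, the time with the highest mean signal, from among the 4 times. With this signal as a covariate, 3721 probe sets passed for ZT18 against ZT12. The covariate ended 3672 of the 7078 calls made without it, so the 3721 include probe sets not called before.

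**Figure D3:**
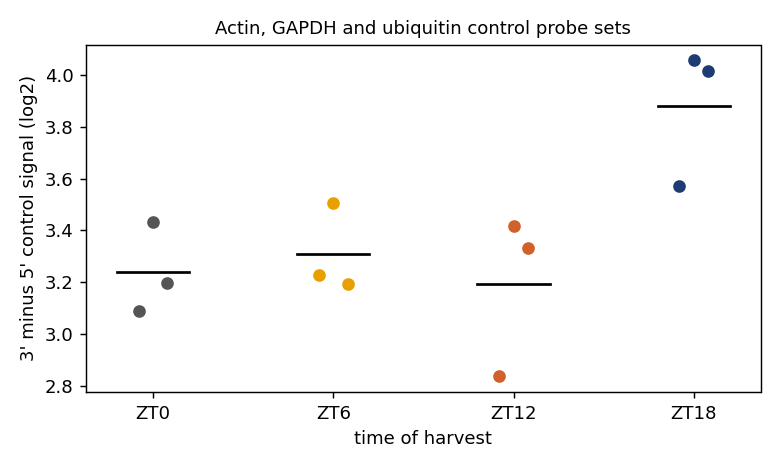
Mean 3' minus 5' signal of 3 control transcripts on the log2 scale (vertical axis) by time of harvest (horizontal axis), with a point per array and a bar at the mean. The 3 ZT18 arrays lay between 3.57 and 4.06, and the highest of the other arrays was at 3.51.

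From ZT18 to ZT0, through the end of the night, HYH, a bZIP factor of light signalling, rose from 7.66 ± 0.88 to 10.86 ± 0.30 (9.21-fold, adjusted p = 2.30e-05). EXPA16 rose 6.97-fold, AT4G15430 8.62-fold and AT1G47400 7.79-fold. Genes that fell included AT5G48570, a co-chaperone gene, which fell 33.1-fold from 9.36 ± 0.68 to 4.31 ± 0.63. AT5G51440, a small heat-shock gene, fell 15.8-fold from 7.46 ± 1.52 to 3.48 ± 0.53, a mean under the detection limit of 4. AT5G12110 fell 15.2-fold, and AT1G53540 fell at least 10.7-fold. AT4G33550 fell 11.4-fold and AT3G46370 at least 3.23-fold. The test called 2600 probe sets as higher at ZT0 and 2587 as lower, 1202 of them at least 2-fold. With the 3' minus 5' covariate 2788 passed. The covariate ended 2880 of the 5187 calls made without it, so the 2788 include probe sets not called before.

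Of the 7 cytosolic ribosomal protein genes, 6 rose from ZT18 to ZT0, also adjusted over the list alone, with a list median of 0.32. Camera did not call the list (adjusted p = 0.0568, and adjusted p = 0.578 with an estimated correlation), the 3' minus 5' signal also differed between these times, and 0 of the 6 still passed by limma with it as a covariate. COR15A and COR15B fell, with or without the covariate, whereas COR47 and LTI30 did not pass. Both starch synthesis genes fell, and 0 of 2 still passed with the covariate. GI fell by 1.45 (SE 0.18). PYK10 fell from 13.19 ± 0.19 to 12.74 ± 0.24, a call that was also lost with the covariate. Of 14 serine carboxypeptidase-like genes 8 fell (camera adjusted p = 0.0154, and adjusted p = 0.662 with an estimated correlation), among them SCPL34 (11.14 ± 0.14 to 9.94 ± 0.23), and 6 of the 8 still passed with the covariate. Of the 25 chloroplast assembly and RNA editing genes 10 fell and none rose (camera adjusted p = 0.0365, and adjusted p = 0.662 with an estimated correlation), and 8 of these 10 still passed.

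Between times 12 h apart, ZT12 exceeded ZT0 for AT1G60590 (48.4-fold), AT2G27420 (47.8-fold), AT3G44970 (at least 17.7-fold) and AT5G59130 (at least 20.3-fold), and AT1G72920 was 9.12 ± 1.23 against 3.48 ± 2.42. ZT0 exceeded ZT12 for AT3G15440 (at least 19.6-fold), EXPA16 (at least 49.9-fold), AT5G02580 (46.6-fold), AT1G19530 (45.6-fold) and XTH33 (31.3-fold). The ZT12 means of AT5G02580 (3.90 ± 0.58) and XTH33 (3.93 ± 0.47) lay under the detection limit of 4, so their folds rest on dim signal. ZT18 exceeded ZT6 for COR27 (59.3-fold), XTH33 (at least 18.9-fold), AT1G50040 (at least 11.2-fold), AT4G33980 (30.0-fold) and AT1G17665 (at least 10.9-fold). ZT6 exceeded ZT18 for AT1G13650 (at least 30.3-fold), AT1G60590 (52.6-fold), AT1G47400 (36.2-fold), AT4G13800 (28.2-fold) and AT1G10640 (25.9-fold). All of these had adjusted p-values of at most 0.000201. For ZT12 against ZT0, 3588 probe sets were higher and 3983 lower. For ZT18 against ZT6, where the 3' minus 5' signal also differed (3.88 against 3.31), 3193 were higher and 3285 lower. Camera called 4 added families as higher at ZT12 than at ZT0: chloroplast assembly and RNA editing (18 of 25 higher, adjusted p = 2.23e-05), UGT (15 of 25 higher and 4 lower, adjusted p = 0.00848), CYP71B (5 of 9 higher and 1 lower, adjusted p = 0.0457) and glutathione S-transferase (5 of 7 higher, adjusted p = 0.0335). With an estimated correlation these calls were lost (adjusted p = 0.651 for CYP71B and adjusted p = 0.648 for each of the others). It called 3 as lower at ZT18 than at ZT6: chloroplast assembly and RNA editing (18 of 25 lower and 1 higher, adjusted p = 0.00119), CYP71B (6 of 9 lower, adjusted p = 0.0154) and glutathione S-transferase (6 of 7 lower, adjusted p = 0.0242). These were lost as well (adjusted p = 0.648 for each with an estimated correlation). With the covariate 11 of the 19, 3 of the 6 and 4 of the 6 genes that passed for ZT18 against ZT6 still passed.

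All 6 ZT6 and ZT12 arrays lay above all 6 ZT18 and ZT0 arrays for 2190 probe sets (15.6%) and below them for 2198. Chance gives 0.108% for each if the 12 arrays are exchangeable, which arrays of 4 differing times are not. For the other ways to pair the times, counted after these values were seen, the numbers were 68 above and 72 below for ZT0 and ZT6 against ZT12 and ZT18, and 172 above and 167 below for ZT0 and ZT12 against ZT6 and ZT18. Of 3871 probe sets higher at ZT6 than ZT0, 2120 were lower at ZT18 than ZT12, against 944.3 expected for independent lists. Of 3980 that were lower, 2212 were higher, against 1039 expected. These comparisons share no array. Across probe sets, which are not independent replicates, their log2 changes had Pearson's r = -0.67.

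Expansin and xyloglucan endotransglucosylase genes, which encode proteins that loosen or remodel the cell wall, went in both directions. Of 18 measured members, 11 were lower and 7 higher at ZT6 than at ZT0. The family as a whole was not called by camera in any comparison (adjusted p = 0.328 for ZT6 against ZT0, and adjusted p = 0.662 with an estimated correlation). XTH33, EXPA16 and EXLB1 were named by the rule, and the members that follow were chosen after their values were seen. EXLA2 was 11.06 ± 0.07 at ZT0 and 7.39 ± 0.63 at ZT6, and XTH18 was 9.53 ± 0.74 and 6.32 ± 0.22. XTH32 was 6.07 ± 0.25 at ZT0 and 9.97 ± 0.10 at ZT6, EXPB3 was 6.55 ± 0.10 and 10.40 ± 0.07, EXPA15 was 4.57 ± 0.10 and 6.72 ± 0.15, and EXPA8 was 8.69 ± 0.21 and 10.04 ± 0.21. All of these differences passed the limma test, with adjusted p-values of at most 0.000132.

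**Figure D4:**
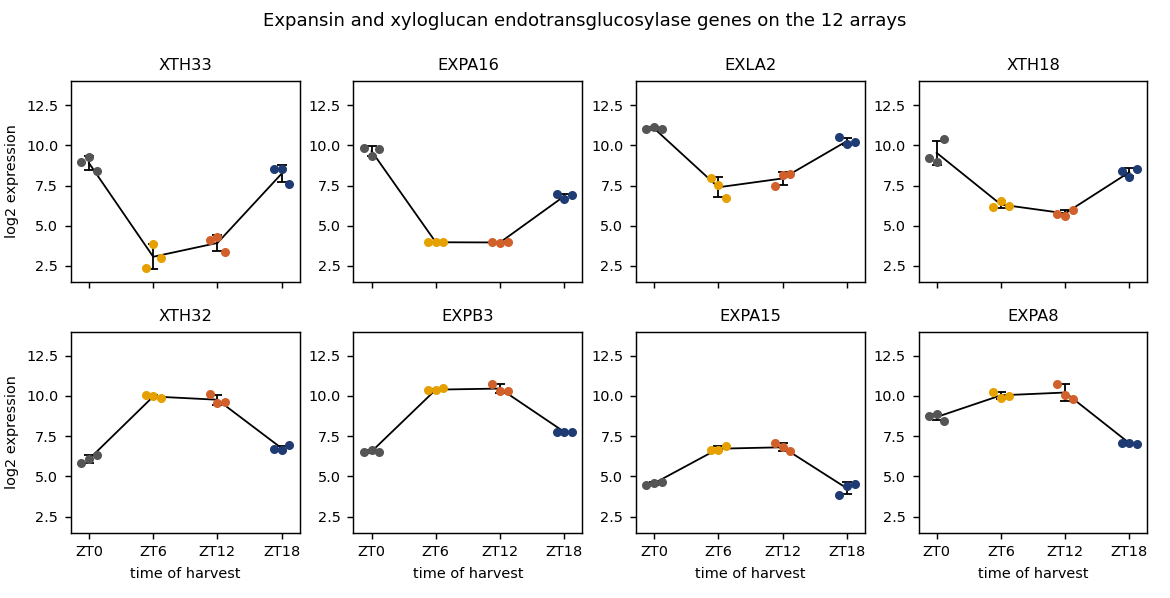
Log2 expression (vertical axis) of 8 expansin and xyloglucan endotransglucosylase genes at the 4 times (horizontal axis), with a point per array and a line through the means with SD bars. XTH33, EXPA16, EXLA2 and XTH18 were higher at ZT0 and ZT18 than at ZT6 and ZT12, and XTH32, EXPB3, EXPA15 and EXPA8 were higher at ZT6 and ZT12 than at ZT18.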

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

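The covariate for the 3' to 5' signal, the F-tests without ZT18 or ZT0 arrays and the settings repeated for the added families were chosen after seeing the data; the rest were chosen before. The count for the 4 times was 9827 and stayed within 1.5 times of that in 23 of 25 alternatives, including 8664 without the ZT18 arrays and 7492 without the ZT0 arrays. Requiring a 2-fold change as well gave 4524 for the 4 times, and 3009, 92, 2225, 1202, 2839 and 2128 for ZT6 minus ZT0, ZT12 minus ZT6, ZT18 minus ZT12, ZT0 minus ZT18, ZT12 minus ZT0 and ZT18 minus ZT6, a smaller set by construction. The contradicting time label gave 0 for the 4 times and 0 in each of the 6 comparisons by limma, with 34 for the 4 times and 16 to 279 in the comparisons at an unadjusted p under 0.05. An adjusted p under 0.01 left 38 for ZT12 minus ZT6 and 3138 for ZT0 minus ZT18. ZT12 minus ZT6 (297) was the least stable: it was 145 with no filter, 752 in a fit to its 6 arrays alone, and 27 to 466 when single arrays were left out, lowest without ZT6 replicate 2; the cause was not tested. The genes named by size were repeated under the other filters, normalizations and variance models, the block, the covariate and with each array left out. In these repeats 8 of those named for ZT12 minus ZT6 missed the threshold at least once, none named for another comparison did, and none changed sign. Under the contradicting label all of them missed it. The 3' to 5' covariate gave 3721 for ZT18 minus ZT12 and 2788 for ZT0 minus ZT18, each including probe sets not called without it.

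Same-numbered arrays did not deviate together throughout: the correlation of their deviations from the time means was -0.15 to 0.40 over 18 pairs and over 0.1 in 9, so the numbers were not taken to pair the arrays, although 11 of 12 arrays correlated best with an array of their own number. All 3 pairs were over 0.1 for ZT0 with ZT12 (0.403, 0.191 and 0.277) and for ZT0 with ZT18 (0.253, 0.185 and 0.322), and not for the other 4 comparisons; this is a hint from the data and not from the design. With the replicate number as a block, ZT12 minus ZT6 gave 815, ZT12 minus ZT0 gave 8089, ZT0 minus ZT18 gave 6004 and the 4 times 10480, and the fixed lists gave 1 call.

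The fixed lists, with 0 of 12 calls by camera (4 at an unadjusted p under 0.05) and 0 with an estimated correlation (0 unadjusted), gave 4 with no filter, 5 with the contradicting label and 0 to 3 when single arrays were left out, the highest without ZT0 replicate 1. The added families, with 19, gave 8 with no filter, 9 with the contradicting label, 0 with an estimated correlation (9 at an unadjusted p under 0.05) and 14 to 29 when single arrays were left out, the highest without ZT18 replicate 1. Fry, which asks whether a list moves 1 way and not whether it differs from other genes, called 7 and 75, so its counts are not set against those of camera.

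Under the 3' to 5' covariate 16 values of list members changed sign, counting only values that passed with or without it. Called values that went to near 0 were AT2G43030 (-0.014 for ZT0 minus ZT18 and 0.005 for ZT18 minus ZT6), AT3G09630 (0.013), GSTU26 (0.003) and SBPASE (0.017) for ZT18 minus ZT12, and psbI (-0.061) for ZT0 minus ZT18. Plastid-encoded genes that passed only with the covariate were psbF (-1.54 for ZT18 minus ZT12 and 1.36 for ZT0 minus ZT18), psbM (0.93 and -1.01) and rps19 (0.56 and -0.44) in those comparisons, rpl33 (0.41) for ZT18 minus ZT12, and rpl14 (0.84), rpl36 (0.48) and rps4 (0.54) for ZT18 minus ZT6. The cause was not tested. Signal near the floor limits the dim genes, whose folds are bounds where all 3 arrays of the dimmer time lay under 4. The folds of AT5G51440 against ZT0 and of AT5G02580 and XTH33 against ZT12 are not bounds, although those means lay under 4.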

Other observations

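For the added families, the test of correlated list members was chosen after its result was seen; for the fixed lists the same setting had been listed in advance. The iron and heat-shock lists were drawn up after the largest changes had been seen. Of 4 measured iron-deficiency genes, 3 had their highest mean at ZT12 and their lowest at ZT18. By limma 1 of the 4 passed for ZT12 against ZT6. For ZT0 against ZT18 3 passed, and 2 of these still passed with the 3' to 5' covariate. BHLH101 was 4.95 ± 0.48 at ZT0, 7.70 ± 0.14 at ZT6, 9.06 ± 0.19 at ZT12 and 3.57 ± 0.46 at ZT18. PYE, another transcription factor gene of iron homeostasis, went from 7.77 ± 0.25 at ZT12 to 5.35 ± 0.24 at ZT18, and AT1G47400 moved as given above. AT1G18910 lay between 4.97 and 5.16 at all 4 times (limma F-test adjusted p = 0.780).

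Heat-shock and co-chaperone genes did not share a time of day. AT1G53540 (7.42 ± 1.60), AT5G48570 (9.36 ± 0.68), AT5G51440 (7.46 ± 1.52) and Hop3 (7.64 ± 1.32) were highest at ZT18. Their spread between arrays was wide there except for AT5G48570, whose SD was similar at ZT0 (0.63). The Hsp70 gene AT3G09440 was lowest there (4.68 ± 0.54) and highest at ZT12 (8.41 ± 0.33), and Hsp70-2 also peaked at ZT12 (8.89 ± 0.17). Hop2 did not pass the F-test (adjusted p = 0.726). Over 12 measured members, 5 rose and 4 fell from ZT12 to ZT18, and 6 of these 9 still passed with the 3' to 5' covariate.

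The grouping by time gave 9827 probe sets, and 1 of 100 splits of the 12 arrays into 4 groups of 3, the real one, gave as many. A chance division of these arrays is thus excluded at 0.05. Chance differences between harvests are not, since the labels do not say whether a time's arrays came from separately grown plants. The highest of the other splits gave 4983. For 3 arrays against 3, 10 splits are too few for a share under 0.05. Every split but the real one mixes arrays of both times, which widens the spread where the times differ. Low counts in those splits are thus not a rate for chance alone. In each comparison 1 split, the real one, gave the most: 7851 against a highest other of 0 for ZT6 minus ZT0, 297 against 36 for ZT12 minus ZT6, 7078 against 0 for ZT18 minus ZT12, 5187 against 0 for ZT0 minus ZT18, 7571 against 0 for ZT12 minus ZT0, and 6478 against 1 for ZT18 minus ZT6.

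The ZT18 arrays had the steepest 3' to 5' gradient, so shortened RNA could account for changes at ZT18. With the gradient as a covariate, the median change of the called probe sets kept 0.889 of its size for ZT18 minus ZT12 (0.75 to 0.67, and 0.829 to 0.904 of its size with each array left out). For ZT0 minus ZT18 it kept 0.965 (0.68 to 0.66, and 0.828 to 1.06). The slope of the covariate came from differences between arrays of the same time, where replicate 2 had the highest signal at every time. It may thus follow the replicate number, so these shares do not decide whether the gradient was the cause. The covariate still ended 3672 and 2880 calls, and wider errors took part, since the median SE of all probe sets grew from 0.157 to 0.234 and from 0.157 to 0.225. The ended calls' median change went from 0.58 to 0.40 and from 0.57 to 0.44, but these probe sets were picked by losing the call, which favours a smaller change, so this does not show how much followed the gradient. That share and the difference in time of day, which the design names, both stay open.

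Besides a difference between times, the 19 calls of added families have other candidate explanations. Whether these are biological was not tested. Of 100 splits of the arrays, 21 gave at least as many list calls as the real grouping, with up to 24. The other splits mix arrays of differing times and so carry real differences, with up to 4983 probe sets passing the F-test. Their list calls are not a count for chance alone, so chance is neither excluded nor shown. With the correlation between members estimated from the arrays, 0 of 162 tests passed in camera (9 at an unadjusted p under 0.05). Fry, which does not compare a list with other genes, passed 75. Members that vary together between arrays could give such a loss of calls. The estimated setting was not tried on simulated lists, so whether it finds a real shift here is not known. The loss of calls therefore does not decide whether members varied together. The counts of single genes that rose or fell in these families rest on the tests of those genes and not on camera.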
